A study of Mus musculus with 2 samples.

How the data were processed

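RNA was profiled on 2 Affymetrix arrays, one hybridised with labelled RNA from mouse NIH 3T3 fibroblasts carrying a plasmid for a C-terminally truncated ATCE1 (the ATCE1-C-del array) and one with RNA from cells carrying the vector without insert (the empty vector array). RNA was taken 48 hours after lipid-based transfection in both cases, per the labels. Each sample was placed in its group by its title or description.

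The deposited intensity values are MAS5 signals on a linear scale, per the submitters' processing notes, which name MAS5 and no version. MAS5 combines the perfect-match and mismatch probes of a probe set into 1 signal. The target value, masks and detection calls are not given in the sources used here. The values themselves show the scaling: the mean after trimming 2% of the probe sets at each end was 250.1 on both arrays, as MAS5 global scaling gives. Each array held 22690 probe sets, of which 64 were AFFX controls that stayed out of the comparison.

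Gene names came from a table of the platform's annotation, which gave 1 symbol for 20393 probe sets, several for 691 and none for 1606. Probe sets with several symbols or none were counted as probe sets but named no gene. Matching the Entrez IDs to a RefSeq gene table of the assembly GRCm38.p6, used for names only, changed 0 symbols. A gene missing from a list below is unnamed in this table, which does not show that the array lacks it. Probe sequences and genome positions were not used here.

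Each array was divided by its trimmed mean (2% to 98%), which left the deposited values almost as they were. A signal under its own array's median (77.4 for ATCE1-C-del, 75.9 for empty vector) was set to that median, because MAS5 signals near background vary by large factors. This floor stands in for a detection call and is not one. The log2 ratio of ATCE1-C-del over empty vector was then taken. A probe set or gene was measured if it lay at or above the floor on at least 1 array. Where only 1 array was above the floor, the fold is a lower bound and is given as "at least". This fails for an empty vector signal between the floors of the arrays. Usp18 was such a case, and its floored ratio took the opposite sign to its signals. For each gene, the probe set with the highest mean log2 signal over both arrays was used, a choice that does not depend on the ratio.

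With 1 array per group there was no replicate, no standard error and no test, so changes were counted by a fixed size: 2-fold over all genes and 1.5-fold for members of gene lists. The only spread available was between different probe sets of one gene. It covers hybridisation and probe design on these arrays and leaves out the variation between cultures, transfections and labelling reactions. The number of arrays limits the precision of every value.

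A set of 23 gene lists was fixed before the data were examined, together with the rule for named genes and all alternatives not described as added. For each list with at least 3 measured members, the median log2 ratio was placed among the medians of 10000 random lists of the same size drawn from the same 20 bins of mean signal. A list was said to stand apart under the 2.5th or over the 97.5th percentile. This percentile describes these 2 arrays and is not a p-value, since genes are not replicates and genes of one pathway vary together. The genes named by rule were Creb3l4, up to 12 genes per direction changed at least 2-fold and above the floor on both arrays, up to 4 per direction with a lower bound where the brighter signal was above its array's 75th percentile (0 genes met this), and up to 4 members of each list with the largest absolute ratio.

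The procedure was tested on simulated data built on the real signals of this comparison (12393 genes). Of 200 genes changed 3-fold, 89% were recovered at 2-fold, and 0 of 11312 unchanged probe sets were called at a simulated SD of 0.2 (log2). Of 200 unchanged simulated lists of 25 genes, 6.5% fell outside the middle 95%, and all 50 lists shifted by 0.25 (log2) were found. The simulated noise was the same for every probe set, so 2-fold was out of reach for nearly all unchanged ones. The real ratios had an SD of 0.24, and simulated list members varied independently, unlike genes of one pathway. The simulation checks the procedure and does not give the rate of false calls on the real arrays. Alternatives covered the scaling (signals as deposited, array medians, quantile normalization, lowess with a span of 0.3), the floor, the log scale, the fold threshold, probe sets that can match several transcripts and the choice of probe set per gene. Scaling to the hybridisation controls, lists without shared members and families of genes with a common symbol stem were added after the data were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.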

Results

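The arrays addressed which transcripts differ in abundance when NIH 3T3 cells, a mouse embryonic fibroblast line, express a truncated form of ATCE1 described as nuclear. ATCE1 is a basic leucine zipper transcription factor of the CREB family whose gene is now called Creb3l4. There was 1 array for the ATCE1-C-del plasmid and 1 for the vector without insert, both from RNA taken at 48 hours, so no value has a replicate error and no test was made. Of 22626 probe sets without controls, 11631 were measured on at least 1 array and 10996 on both, and these stood for 6806 and 6521 genes. Log2 signals of the probe sets measured on both arrays correlated across probe sets with a Pearson r of 0.985, probe sets not being independent replicates, and 97.7% of them lay within 1.5-fold. The middle 95% of their log2 ratios ran from -0.49 to 0.47. Among 2451 genes with a second probe set measured on both arrays, the ratios of the 2 brightest probe sets correlated across genes with an r of only 0.29, and 1 probe set's log2 ratio carried an SD of 0.20 from this source alone.

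Creb3l4 itself was not measured above the floor. Its single probe set had a signal of 18.0 on the ATCE1-C-del array and 20.7 on the empty vector array, both far under the floors of 77.4 and 75.9. The position of its probes relative to the truncated insert is not given in the sources used here, so these signals do not check which culture carried the insert.

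At 2-fold, 5 genes were higher and 2 were lower with ATCE1-C-del. Tcl1b3, a member of the Tcl1 oncogene family, was 13.2-fold higher, with a signal of 5255 against 399. The chemokine gene Ccl5 was 4.43-fold higher, at 402 against 90.6. Gtse1, which encodes a microtubule-associated protein of G2 and S phase, was 2.39-fold higher, at 201 against 84.1. Atf3, a stress-induced member of the ATF family, was 2.13-fold higher, at 188 against 88.1, and Plaur, the urokinase receptor, was just over 2-fold higher, at 165 against 82.2. Rusc1 was 2.23-fold lower, at 97.9 against 218, and Gpr85, an orphan receptor, was 2.03-fold lower, at 110.0 against 223. The 5 higher genes each had no other measured probe set. The other measured probe set of Rusc1 was at least 1.21-fold lower, with the ATCE1-C-del signal under the floor, and those of Gpr85 were 1.28-fold lower and, with the same limit, at least 1.04-fold lower. Tcl1b3, Rusc1 and Gpr85 were read by probe sets that can match several transcripts, as was Plaur, and leaving such probe sets out left 3 of the 5 higher genes and 0 of these 2 lower genes. With the floor at each array's 75th percentile (308 and 315) only Tcl1b3 remained. The choice of floor fixes this, since the others except Ccl5 lie under it on both arrays. The empty vector signal of Ccl5, 90.6, was raised to that floor, which held its log2 ratio to 0.35. With scaling to the hybridisation controls, chosen after the data were seen, 14 genes were higher and 0 lower.

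**Figure D1:**
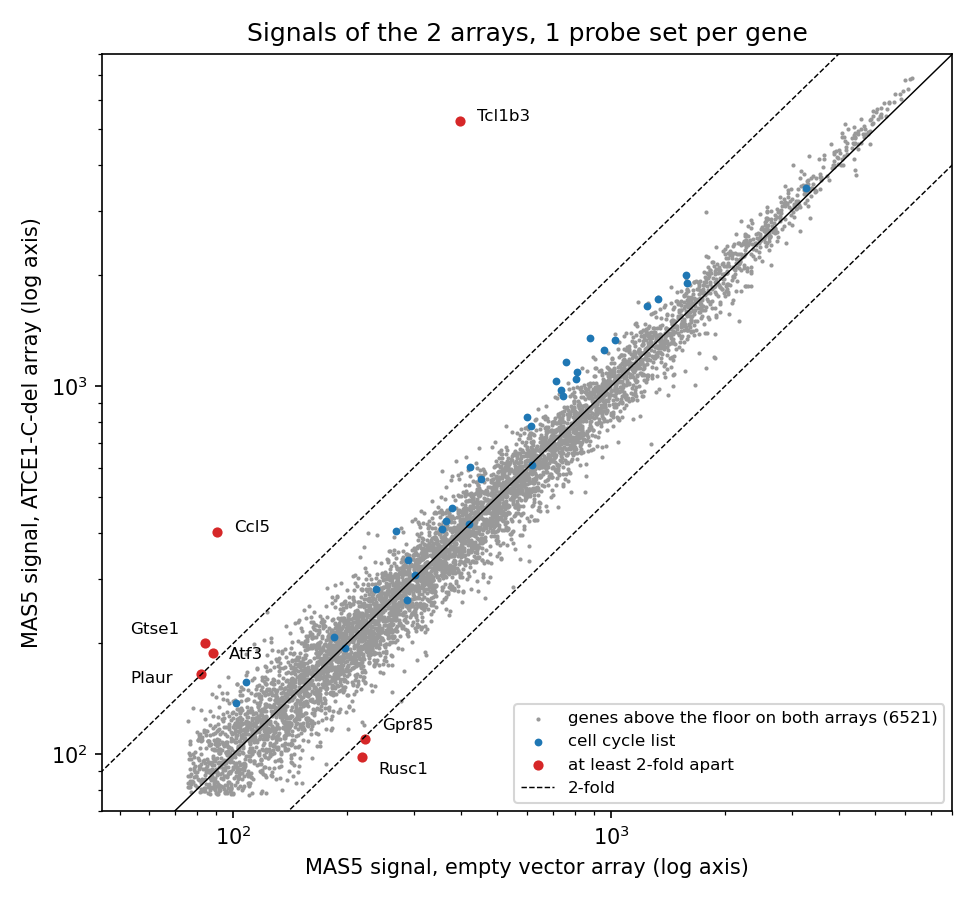
MAS5 signal on the ATCE1-C-del array against that on the empty vector array, both on log axes, for the 6521 genes above the floor on both arrays, with 1 probe set per gene and 1 array per group. Red points are the 7 genes at least 2-fold apart, of which Tcl1b3 lies at 5255 against 399, blue points are the measured cell cycle genes, which lie mostly above the line of equality, and dashed lines mark 2-fold.

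Counted by probe set, 9 were at least 2-fold higher and 8 at least 2-fold lower. Those that do not stand for their gene were chosen after their values were seen. Among the higher ones, Fmr1 (2.10-fold) and Ccm2 (2.11-fold) had a brighter probe set that went the other way, at log2 ratios of -0.26 and -0.18, and a further one on the same side, at 0.60 and 0.17. Another 2 probe sets have no gene name in the table used and were at least 3.88-fold higher, at 294 against 26.1, and at least 2.28-fold higher, at 173 against 20.3. Among the lower ones, Sumf1 was 2.20-fold lower and its brighter probe set 1.53-fold lower, and all 6 measured probe sets of Klf9 were lower, from -0.09 on the brightest to -1.05 in log2 ratio. The brightest probe sets of Dram2, Itsn1, Tmem33 and Tor1b lay between -0.23 and 0.07, and further ones lay at -0.35 for Itsn1, 0.17 for Tmem33 and 0.00079 for Tor1b. At 1.5-fold, 63 genes were higher and 73 lower. Of 43 genes whose brightest probe set was changed at least 1.5-fold and that had a second one measured on both arrays, 31 had the second on the same side, where 60.2% of all 2451 genes with such a pair did.

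Genes of the cell cycle had the highest median of the lists scored. Of 33 measured members, 30 were higher with ATCE1-C-del and 3 lower, with a median log2 ratio of 0.35 (1.28-fold). Only 2 members passed 1.5-fold: Cenpa, the centromeric histone H3 variant, at 1.54-fold and Mcm2, a subunit of the replicative helicase, at 1.53-fold. Kif11, a mitotic kinesin, was 1.49-fold higher, with its other probe sets at log2 ratios of 0.48 and 0.50. Mcm4, of the same helicase as Mcm2, was 1.45-fold higher, with its other probe set at 0.20. The other probe set of Mcm2 went the opposite way, at -0.45. Chosen after their values were seen, Mcm3 (0.34), Mcm5 (0.51), Mcm6 (0.41) and Mcm7 (0.35) were also higher in log2 ratio on their brightest probe sets, 1 of the other probe sets of Mcm7 lying at -0.16. Mki67 (-0.02), Cenpe (-0.02), Cenpf (0.01) and Kif20a (0.02), which serve mitosis or mark cycling cells, were level and E2f1 stood at -0.13. Other mitotic genes were higher, such as Ttk (0.53), Aurka (0.31), Bub1b (0.30) and Plk1 (0.24), and the replication gene Pcna was near level (0.08). These values do not separate replication from mitosis. The list median lay above those of all 10000 matched random lists, whose middle 95% ran from -0.09 to 0.07. It stood apart under all 10 alternatives in which lists were scored. Of these, 2 (signals as deposited and array medians) shift all ratios alike and cannot change a percentile. Quantile normalization and lowess adjust for a trend with signal, which the matched random lists mostly share. Of 16 lists scored, 5 stood apart as higher and 3 as lower. If members varied independently, 0.8 would be expected outside the middle 95%. Genes of one pathway vary together and some lists share members, so this number does not measure chance here.

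Serum response and immediate early genes, which growth factors and stress induce within minutes to hours, were also higher. Of 28 measured members, 22 were higher and 6 lower, with a median log2 ratio of 0.24 (1.18-fold), and 5 passed 1.5-fold, all higher. These were Atf3 and Plaur, given above, the AP-1 subunit Fosl1 at 1.75-fold, Fos at least 1.64-fold and, outside the naming rule, the MAP kinase phosphatase Dusp6 at 1.52-fold. The second probe set of Fosl1 had a log2 ratio of at least 0.04, with signals of 78.0 and 44.9, the latter under the floor. The list lay above the random range of -0.12 to 0.08, but with the floor at the 75th percentile its median was 0.0047 and it no longer stood apart. The second-brightest probe sets of 8 of these genes had a median of 0.0074, with 4 of 8 higher, whereas those of 13 cell cycle genes had a median of 0.24, with 12 higher.

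Genes inducible by cAMP, the signal to which CREB proteins respond, had 12 of 16 measured members higher and a median log2 ratio of 0.26 (1.20-fold). Ptgs2, which encodes cyclooxygenase-2, was 1.65-fold higher and its other probe set had a log2 ratio of 0.97, and Fos was at least 1.64-fold higher. The nuclear receptor gene Nr4a1 was 1.42-fold higher and the bZIP repressor gene Nfil3 1.41-fold higher. The list lay above the random range of -0.13 to 0.11. However, 7 of the 16 members also belong to another of the lists, and the 9 that do not had a median of 0.09, at the 88.6th percentile, inside the random range of -0.19 to 0.16. With the floor at the 75th percentile the whole list also no longer stood apart, at the 94.8th percentile.

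Members of the CREB and ATF family lay on both sides of 0. Of 13 measured members, 8 were lower and 5 higher, with a median log2 ratio of -0.23, under the random range of -0.16 to 0.15. Atf3 was 2.13-fold higher, and Atf5, which responds to amino acid and protein stress, was 1.66-fold lower at a signal of 1004 against 1665. The coactivator gene Crebbp was 1.34-fold lower and Creb3l2, a close relative of Creb3l4, 1.24-fold lower. The other measured probe set of Creb3l2 was level, at a log2 ratio of -0.02. The median of this list no longer stood apart under 4 of the 10 alternatives, including the average over all probe sets of a gene, where it was -0.077.

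Extracellular matrix genes, interferon-induced genes and the CREB family formed the lists that stood apart as lower. Of 30 measured matrix genes, 20 were lower and 10 higher, with a median log2 ratio of -0.06 against a random range of -0.02 to 0.09. Postn, which encodes periostin, was 1.58-fold lower, and the basement membrane collagen genes Col4a2 and Col4a1 were 1.43-fold and 1.26-fold lower, whereas the protease inhibitor gene Timp1 was 1.34-fold higher. Of 16 measured interferon-induced genes, 11 were lower and 5 higher by floored ratio, and 0 passed 1.5-fold. The median was -0.17 against a random range of -0.13 to 0.13. Usp18 counted as higher only because the floors of the arrays differ, its signals being 73.3 against 76.5. Gbp2 was 1.38-fold lower on one probe set and -0.48 in log2 ratio on its other, Ifit2 and Ifit3 were 1.27-fold and 1.23-fold lower, and the GTPase gene Irgm1 was 1.33-fold higher. The matrix list stood apart under all 10 alternatives and the interferon list under 7. For both, these include signals as deposited and array medians, which cannot change a percentile. The interferon list no longer stood apart with the floor at the 25th or 75th percentile or with no floor, so its call depends on the floor. All 3 medians are relative to the other genes on the arrays: scaled to the hybridisation controls, the median of all measured genes moved to 0.24 and those of the CREB family, matrix and interferon lists to 0.011, 0.19 and 0.072, so that their sign reversed.

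The 14 measured NF-kB targets did not stand apart. Of these, 7 were higher and 7 lower, and only Ccl5 passed 1.5-fold. The median log2 ratio was -0.01 and the mean 0.14, which differ in sign because of Ccl5. Birc3, an inhibitor of apoptosis, was 1.39-fold higher and Ccl7 1.22-fold higher, while Nfkbia, which encodes the NF-kB inhibitor, was 1.35-fold lower with its other probe sets at log2 ratios of -0.34 and -0.29.

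Heat shock and proteasome genes were slightly higher, with 19 of 21 measured members above 0 and a median log2 ratio of 0.11 against a random range of -0.06 to 0.10. The inducible chaperone gene Hspa1a was at least 1.99-fold higher, with a signal of 151 against 8.50. Hspa1b, outside the naming rule and brighter, was only 1.17-fold higher, at 1016.5 against 865.7. The co-chaperone gene Dnajb1 was 1.48-fold higher, with its other probe set at a log2 ratio of 0.02. Hsp90aa1 was 1.21-fold higher, while Bag3 was 1.38-fold lower. Genes of amino acid and glycolytic metabolism had a median of 0.12 against a random range of -0.06 to 0.10, with 15 of 22 members higher and 0 past 1.5-fold. The glycolytic genes Aldoa and Ldha were 1.27-fold and 1.17-fold higher, and Hk2 and Bnip3 were 1.21-fold and 1.17-fold lower.

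Genes of the unfolded protein response, which relatives of Creb3l4 in the endoplasmic reticulum can serve, did not stand apart. All 29 measured members lay within 1.5-fold, with 18 higher and 11 lower and a median log2 ratio of 0.03 in a random range of -0.08 to 0.08. The extreme members were Sesn2 at 1.26-fold higher, the chaperone gene Hyou1 at 1.21-fold higher, Trib3 at 1.19-fold lower, with its other probe set at a log2 ratio of 0.12, and Pdia6 at 1.18-fold lower. The 28 secretory pathway and vesicle coat genes also all lay within 1.5-fold, with a median of 0.02, from Kdelr2 at 1.18-fold and Lman1 at 1.15-fold higher to Sec24b at 1.16-fold and Sec23a at 1.12-fold lower. The other probe sets of Kdelr2 and Sec24b went the opposite way, at log2 ratios of -0.16 and 0.02, and those of Lman1 went both ways, at 0.22 and -0.15. Single arrays cannot show that these genes were unchanged.

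The remaining lists did not stand apart. Growth arrest and p53 targets had a median log2 ratio of -0.07, with 14 of 23 members lower, and included Btg2 at 1.42-fold higher and Trp53inp1, Sesn1 and Zmat3 at 1.41-fold, 1.40-fold and 1.38-fold lower. The oxidative stress list had a median of 0.04, with the quinone reductase gene Nqo1 at 1.47-fold higher and Gstm1 at 1.39-fold lower, Hmox1 at 1.13-fold higher and Gsta4 at 1.13-fold lower. The sterol synthesis list had a median of 0.02 and a mean of -0.01, with Acaca and Scd2 at 1.28-fold and 1.15-fold higher and Dhcr7 and Msmo1 at 1.26-fold and 1.14-fold lower. The cytoskeleton list had a median of 0.04, with Tpm4 and Tpm1 at 1.18-fold and 1.09-fold higher, other probe sets of Tpm1 lying at log2 ratios of 0.12 and -0.16, and Tagln and Cnn2 at 1.24-fold and 1.13-fold lower. The ribosomal protein list had a median of 0.09, with 18 of 19 members higher, among them Rps4x at 1.16-fold, Rpsa at 1.12-fold, Rps15 at 1.11-fold and Rpl8 at 1.10-fold higher, within a random range of 0.0037 to 0.12 for genes this bright, and quantile normalization and lowess turned the median to -0.018 and -0.0015.

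**Figure D2:**
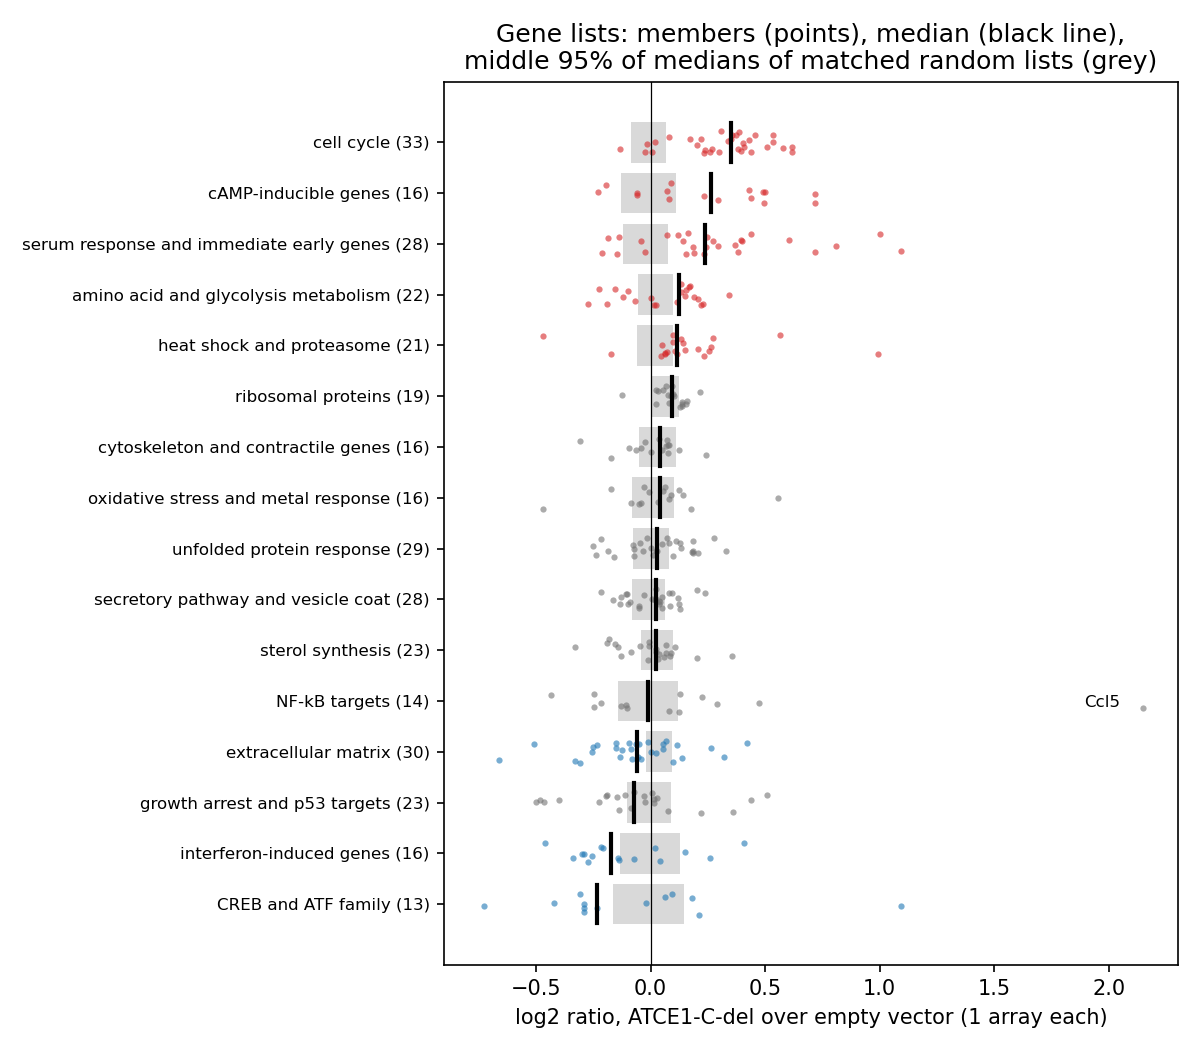
Log2 ratio of ATCE1-C-del over empty vector (1 array each) for the members of the 16 gene lists with at least 3 measured members, whose number stands in brackets. Points are genes, black lines the list medians and grey bars the middle 95% of medians of matched random lists; the 5 lists in red lie above their bar, led by cell cycle at 0.35, and the 3 in blue lie below it, with the CREB and ATF family lowest at -0.23.

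Markers of other cell types were nearly absent from the measured genes. None of the 11 epithelial, 13 muscle and 10 endothelial markers on the arrays reached the floor, and 2 of 12 macrophage markers did, Cd14 at 1.11-fold higher and Cd68 at least 1.07-fold higher. Among 9 adipocyte markers only Lpl, also expressed by fibroblasts, was measured, at 1.42-fold lower. Of 34 spermatid-expressed genes on the arrays, the cell type in which Creb3l4 is normally active, only Odf2, a centrosomal protein as well, was measured, at 1.05-fold lower with its other probe set the opposite way, at a log2 ratio of at least 0.26. RNA quality was similar by the control probe sets: the ratio of 3' to 5' signal was 1.07 with ATCE1-C-del and 1.12 with empty vector for Actb, and 0.902 and 0.772 for Gapdh. The 18 hybridisation control probe sets, which read RNA added before hybridisation, had a median log2 ratio of -0.25. Their ratios ran from -0.68 to 0.005, and 17 of them were lower on the ATCE1-C-del array. By their names they read only bioB, bioC, bioD and cre, each by several probe sets, so they are not separate observations.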

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

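The comparison with other control probe sets was chosen after the data were seen. The control probe sets take no part in the comparison above. One of them, AFFX-MUR_b2_at, had a signal of 368.9 on the ATCE1-C-del array and 134.9 on the empty vector array, a ratio of 2.73, and was singled out because it was at least 2-fold apart, above the level in the control culture. By its name it reads a mouse B2 repeat. The other B2 probe set, AFFX-MURINE_B2_at, read 5572 against 5086 (1.10-fold), and the B1 probe set, AFFX-MURINE_b1_at, 3522 against 3122 (1.13-fold). No explanation was tested.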

How the results depend on the processing

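Scaling to the hybridisation controls and lists without shared members were chosen after the data were seen. Leaving out a replicate was not possible with 1 array per group. Counts at 2-fold depended on the floor. The main counts were 9 higher and 8 lower probe sets and 5 higher and 2 lower genes. With the floor at the 25th percentile they became 437, 103, 261 and 37. With no floor they became 2219, 1265, 1203 and 626, and at the 75th percentile 1, 0, 1 and 0. With log2(signal + 25th percentile) they were 26, 4, 15 and 1. At 1.5-fold they were 130, 162, 63 and 73, and at 3-fold 3, 0, 2 and 0. Without probe sets that can match several transcripts there were 4 and 3 probe sets and 3 higher genes. Averaging all probe sets of a gene left 0 lower genes. The dim signals that a low floor lets in leaned to the ATCE1-C-del array, and the cause was not tested. The other scalings planned (as deposited, median, quantile, lowess) left 4 or 5 higher and 2 or 3 lower genes, and where 4 were left Plaur, just over 2-fold, was the one lost. Scaling to the hybridisation controls gave 37 higher and 0 lower probe sets and 14 higher and 0 lower genes. It moved every ratio up, by construction: the list medians became 0.60 (cell cycle), 0.51 (cAMP-inducible), 0.48 (immediate early), 0.37 (amino acid and glycolysis), 0.36 (heat shock and proteasome), 0.19 (matrix), 0.072 (interferon) and 0.011 (CREB family), the last 3 with their sign reversed. Such a constant, like the signals as deposited and the array medians, cannot change a percentile among random lists, so these settings say nothing about which lists stand apart. The number of lists standing apart, 8, became 5 with the floor at the 75th percentile, where the immediate early median was 0.0047. Over the other settings it lay between 6 and 9. The NF-kB and p53 lists stood apart only when all probe sets of a gene were averaged. Without shared members, 31 cell cycle and 22 immediate early genes kept medians of 0.35 and 0.19 and stood apart, and 9 cAMP-inducible genes (0.09) did not. Under the alternatives set beforehand, 641 log2 ratios of named genes moved by less than 0.20, the SD of 1 probe set, and 24 by more. Many of the 641 could hardly move. Signals as deposited and array medians shift all ratios alike, by less than 0.20. A lower floor leaves genes above the main floor on both arrays as they were. A named gene not measured under a setting gave no value there, so its loss is not counted. The hybridisation controls moved 70 values by their constant. Hspa1a, dim in the control, had a log2 ratio of 4.15 with no floor against 0.99. Lowering or removing the floor could not change the calls of the 7 genes at 2-fold, which lie above the main floor on both arrays. Adding the 25th percentile in place of a floor lost Plaur and Gpr85. The loss of 5 of the 7 genes at the 75th percentile follows from their signals, under that floor on both arrays. That of Ccl5 follows from its empty vector signal, which was raised to that floor. Signal over background limits the folds of genes dim on 1 array, which are bounds.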

Other observations

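The families by symbol stem, the single genes of the next paragraph, and the tests of the other Tcl1b genes, of probe binding and of the cultures were chosen after the data were seen. Beyond the fixed lists, genes were grouped by the stem of their symbol. Of 99 families with at least 8 measured members, 10 had a median above the middle 95% of matched random lists and 4 below it. If members varied independently, 2.48 would be expected on each side. Related genes can vary together, so this number does not measure chance here. The Mcm family had the highest median, 0.42 in log2 ratio, with 7 of 8 members higher. Nucleoporin genes (Nup) had a median of 0.20 with 13 of 15 higher, Lsm genes of RNA processing 0.25 with 6 of 9 higher, the splicing factors of the Srsf family 0.19 with 7 of 9 higher, and the nucleolar Nop genes 0.19 with 6 of 8 higher. The proteasome stems Psmb and Psmd stood at 0.16 and 0.12, the phosphatases of the Dusp family at 0.18, the Rad genes at 0.16 and the mediator subunits (Med) at 0.09. On the other side, 59 of 99 zinc finger genes (Zfp) were lower with a median of -0.07, as were 11 of 15 collagen genes with a median of -0.08. The Abhd and Fam stems stood at -0.19 and -0.10. After quantile normalization and after lowess, all 14 stayed outside the middle 95% on their side. The random lists are matched on signal, so these settings test little beyond the main one. With the hybridisation controls, which add a constant, the medians of Zfp, Col, Abhd and Fam turned to 0.17, 0.16, 0.060 and 0.15. The Mcm, proteasome, Dusp and collagen stems hold members of the fixed lists and are no independent evidence.

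Several single genes under 2-fold had more than 1 measured probe set. Tfrc, the transferrin receptor, was 1.46-fold and 1.66-fold higher on its brightest probe sets and at least 1.07-fold on a dim one, and its 3' control probe set was 1.63-fold higher. Hmga2, a chromatin protein of proliferating cells, was 1.67-fold, 1.58-fold and 1.11-fold higher on its 3 probe sets. Rpa2, a subunit of the single-stranded DNA binding complex, was 1.64-fold and 1.47-fold higher. Malat1, a long nuclear RNA, was 1.82-fold, 1.48-fold and 1.67-fold lower on its 3 brightest probe sets, and its 2 dim ones were higher, by 1.10-fold and at least 1.10-fold. In other genes the probe sets differed: Cnot4 had log2 ratios of -0.99, -0.30, 0.07 and -0.07, Adi1 -0.95 and 0.04, Kif22 0.64, 0.02 and 0.22, and Irf3 0.59 and 0.15. E2f4, at 1.99-fold higher on its only probe set, missed the 2-fold count.

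Tcl1b3 was 13.2-fold higher. The scaling cannot account for it, since the lowest log2 ratio over the scaling alternatives was 3.68. Whether other Tcl1b genes were higher too stays open, since the probe sets of Tcl1b1 and Tcl1b4, at or under a signal of 26.5, lay far under the floor on both arrays. The value rests on 1 probe set of a type that can match several transcripts, so whether another transcript, such as one of the plasmid, binds it cannot be told apart from expression of Tcl1b3 without the probe sequences. That ATCE1 raises Tcl1b3 is a hypothesis these arrays leave open.

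Cell cycle genes were higher in the ATCE1-C-del culture, and whether more of its cells were replicating was not measured. A trend with signal was argued against by the matched random lists, which mostly share such a trend, since the median lay above all 10000. After lowess the median was still 0.35 and above all 10000. Matching on signal leaves lowess little room to change this percentile. Faults of single probe sets were argued against too, but only for 13 of the 33 measured genes. Their second-brightest probe sets had a median of 0.24, with 12 higher, at the 99.9th percentile. The other genes had no second measured probe set, so this explanation was not checked for them. What also stays open is a difference between the 2 cultures other than ATCE1, such as density or transfection stress. There was only 1 culture per group. Stress genes were partly higher too (heat shock and proteasome median 0.11, Atf3 2.13-fold), while the unfolded protein response (0.03), oxidative stress (0.04) and p53 lists (-0.07) did not stand apart, which does not separate stress from ATCE1.

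The immediate early genes rested on less. Their median lay above the range of random lists matched on signal, and after lowess it was 0.25. A trend with signal therefore does not account for it. However, the second-brightest probe sets of 8 of these genes had a median of 0.0074 with 4 of 8 higher, at percentile 49.3. Faults of single probe sets would give this, but the floor also pulls dim probe sets toward 0. That of Fosl1, at 78.0 against 44.9, entered at a log2 ratio of 0.04. Only 8 of the 28 measured genes were covered, so these values cannot decide between the explanations. The higher level of this list may rest on single probe sets, which stays open, and that it follows from ATCE1 remains a hypothesis.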
